A study of Mus musculus with 160 samples.

How the data were processed

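The samples were striatum, cortex, cerebellum and liver of R6/2 and wild-type (WT) mice at 12 weeks, 6 h after a single oral dose of vehicle or 10 mg/kg CHDI-00340246. Each of the 16 groups held 10 libraries, 5 per sex, and all 160 libraries were used. Per the labels, total RNA was extracted with miRNeasy columns and sequenced on an Illumina instrument. Base calling used CASAVA 1.8.2 per the submitters' processing notes. The aligner, the counting program and the genome build behind the values are not given in the sources used here.

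The authors deposited estimated counts per gene, which are read counts assigned with fractions, and 73.4% of the values above 0 were whole numbers. The authors also deposited FPKM values, which are fragment counts scaled by gene length and library total. Both tables list 39179 genes by Ensembl identifier, of which 37607 received a symbol and coordinates from GENCODE M21 (GRCm38). The estimated counts were rounded to whole numbers and used for every main result, and FPKM served as an alternative unit.

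Columns were joined to samples by the library name in the labels. Xist and Ddx3y counts matched the labelled sex in 160 of 160 count columns. In the FPKM table only 13 of 160 columns correlated best with the count column of the same header, while 160 correlated best with a count column of the same tissue, genotype and treatment (lowest best correlation 0.992). The sex in the FPKM headers matched Xist and Ddx3y in 72 of 160 columns. FPKM columns were therefore used by group and not by single library. The FPKM fits thus have no sex term, and the genotype by sex interaction has no FPKM alternative. No 2 libraries of the same group were copies of each other.

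The estimated counts per library averaged 36.54 M with an SD of 3.69 M (M, 10 to the power of 6; n = 160). Filtering with filterByExpr left 17494, 17554, 17206 and 15145 genes in the striatum, cortex, cerebellum and liver, which held 99.97, 99.97, 99.97 and 99.98% of the counts. Biological coefficients of variation were 0.161, 0.146, 0.166 and 0.246, and TMM factors ran from 0.89 to 1.1, 0.95 to 1.06, 0.96 to 1.05 and 0.78 to 1.14. In the liver the 10 most abundant genes of a library took 16.88 to 22.77% of its counts.

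Each tissue was fitted alone with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, with 8 cell means for genotype, treatment and sex. The contrasts were the genotype effect under vehicle, the drug effect in WT, in R6/2 and averaged over both, the interaction of drug and genotype, and the interaction of genotype and sex under vehicle (effect in females minus effect in males). P-values were adjusted by Benjamini-Hochberg within each tissue and contrast, and a gene passed at an adjusted p under 0.05. Fold changes are the log2 estimates of the edgeR fit. A prior count of 2 was used for log2 CPM values and not for these fold changes. Lists of genes for pathways, stress responses and cell types, 42 in all with 28 or 29 per tissue, were tested with camera at a correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1). A list needed 5 measured members. The lists, the contrasts and most alternatives were fixed before the data were examined.

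The genes named in the text followed a rule set at the same time. For each tissue and contrast it takes up to 6 of the largest increases and 6 of the largest decreases among passing genes with a mean of at least 1 CPM, leaving out predicted genes and, for the sex interaction, Xist and Y-linked genes. It adds up to 4 passing members with the smallest p from each list, the kynurenine pathway genes, Kmo and Htt. Where no gene passed, it takes the 3 with the smallest p. Genes of the additional observations were chosen after their values were seen. Some genes that the rule takes are not reported here.

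Whether the drug effect runs against the genotype effect in R6/2 was measured by a correlation across genes, with the R6/2 vehicle libraries divided between the 2 effects over 200 halvings. Its p-value and that of the correlation of drug effects in WT and R6/2 came from 100000 relabelled data sets, adjusted over 8 tests. Each count of passing genes was also compared with those of 100 labelled sets of the libraries, the true one included, by limma-trend. For the genotype effect the sets moved genotype labels within sex, and for the drug contrasts treatment labels within genotype and sex. For the sex interaction they moved sex labels within genotype. The rule for reading this comparison was written after the results were seen.

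The alternatives were DESeq2 1.42.0, RLE factors, no filter, sex as an additive term, the replicate number as a block (10 blocks of 4 libraries), the run of library numbers as a covariate (4 runs of 40), limma-trend on log2 FPKM with a pseudocount of 1, and leaving out each replicate number in turn (8 libraries). A further 4 leave-outs were chosen after the data were seen, which removed the library farthest from its group, the chromosome 7 window that starts at 80 Mb, the striatum and cortex libraries with Gh above 5 CPM (6 and 7), and the liver libraries with Saa1 above 1000 CPM (5). The library run as covariate for the correlation of drug effects in WT and R6/2, fitted within each genotype, was also added after the data were seen. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and the R package data.table (1.17.8), and figures drawn with matplotlib 3.10.9.

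The steps were tested on simulated data with 200 changed genes per tissue. For the genotype contrast 52.2, 68.7, 58.2 and 37.9% of genes with a fold of 1.25 were recovered in the striatum, cortex, cerebellum and liver, and 92.4, 92.4, 90.9 and 83.3% of those with a fold of 2. False calls numbered 8 of 167, 15 of 183, 10 of 172 and 1 of 130. For the drug contrast in R6/2 the recovery at a fold of 1.25 was 58.2, 56.7, 56.7 and 35.8%, with 12 of 174, 12 of 173, 11 of 169 and 8 of 137 false calls. Data simulated without a change gave 0 calls in each tissue. A covariance put in at -0.02676, -0.02681, -0.0275 and -0.02728 was returned as -0.02517, -0.02447, -0.02946 and -0.02676. A search for genes at separate levels found 60 of 60 planted genes and 0 others. The planted levels lay 10 times the SD within groups apart, so the recovery of closer levels was not tested.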

Results

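Total RNA from the striatum, cortex, cerebellum and liver of 12-week-old mice was sequenced in 160 libraries, 40 from each tissue. The mice were R6/2 animals, which carry a fragment of the human huntingtin gene with an expanded CAG repeat and serve as a model of Huntington's disease, or wild-type (WT) animals. Both genotypes had received a single oral dose of vehicle or of 10 mg/kg CHDI-00340246, an inhibitor of kynurenine 3-monooxygenase (Kmo), an enzyme of tryptophan breakdown, and tissues were taken 6 h later. Each of the 16 groups of tissue, genotype and treatment held 10 libraries, 5 from females and 5 from males. Library totals ran from 30.2 to 46.3 M estimated counts (M, 10 to the power of 6) in the striatum, 28.5 to 44.25 M in the cortex, 30.5 to 44.4 M in the cerebellum and 34.6 to 45.9 M in the liver, with a mean of 36.5 ± 3.69 M (SD, n = 160). At this depth 17494, 17554, 17206 and 15145 genes passed the expression filter in the striatum, cortex, cerebellum and liver. Xist and Ddx3y counts matched the labelled sex in 160 of 160 libraries. The labels give the background as C57BL/6J in all 160 libraries and number the specimens of a tissue separately, but do not state which specimens come from the same animal, so p-values measure the spread between these samples.

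The drug target and the disease gene were examined first. Kmo (ENSMUSG00000039783, chromosome 1, 175620381 to 175662116, GRCm38) was abundant in the liver, at 333 ± 47.8 CPM (counts scaled to library size; SD, n = 10) in vehicle-treated WT animals. In the striatum of the same group it stood at 0.257 ± 0.145 CPM, in the cerebellum its mean over all libraries was 0.615 CPM, and in the cortex it did not pass the expression filter. Mouse Htt, the homologue of the transgene, did not pass in the striatum (log2 fold change of R6/2 over WT -0.04 ± 0.06, SE, edgeR adjusted p = 0.62, higher than the WT mean in 6 of 10 R6/2 libraries), in the cerebellum (0.03 ± 0.07, edgeR adjusted p = 0.79) or in the liver (0.09 ± 0.1, edgeR adjusted p = 0.54). In the cortex it rose by 0.14 ± 0.05 (edgeR adjusted p = 0.0098, higher in 9 of 10 R6/2 libraries), a call that was lost without replicate 3 (adjusted p = 0.064) or replicate 4 (0.096) of every group. Reads of the human transgene were not analysed here.

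The vehicle groups show what the transgene changed at this age. In the striatum, genes of medium spiny neurons, the main projection neurons of this region, were lower in R6/2 animals. Scn4b, a sodium channel subunit (ENSMUSG00000046480, chromosome 9, 45138395 to 45154152), dropped from a mean of 1689.5 to 167 ± 22.7 CPM (SD, n = 10 per group), a log2 fold change of -3.34 ± 0.08 (SE, edgeR adjusted p = 9.3e-28). Penk, which encodes the enkephalin precursor of indirect pathway neurons (chromosome 4, 4133531 to 4138819), fell from 1454 ± 239.6 to 305 ± 26.4 CPM (-2.25 ± 0.09, edgeR adjusted p = 1.1e-21). Pdyn, the dynorphin precursor of direct pathway neurons, fell from 130.5 ± 11.7 to 67.5 ± 9.27 CPM (-0.95 ± 0.09, edgeR adjusted p = 2e-11). The regulator of dopamine receptor signalling Rgs9 (-1.87 ± 0.07) and the adenylyl cyclase Adcy5 (-1.73 ± 0.06) fell as well, and all 5 genes lay below the WT mean in 10 of 10 R6/2 libraries. Of 29 measured medium spiny neuron genes 27 fell and 1 rose, with the same numbers adjusted over the list alone, a median of -1.48 and adjusted p = 2.1e-62 by camera (0.00061 with an estimated correlation).

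Other neuronal groups of the striatum moved in the same direction. Chat, the acetylcholine-synthesising enzyme of cholinergic interneurons, fell from 32.7 ± 2.62 to 8.64 ± 1.06 CPM (-1.92 ± 0.08, edgeR adjusted p = 1.6e-21), and 12 of 18 interneuron genes fell while 1 rose (median -0.54, camera adjusted p = 0.0037 with an estimated correlation). Immediate early genes, which neuronal activity induces, were lower: 19 of 22 fell and 1 rose (2 rose adjusted over the list alone), among them Npas4 (38.5 ± 7.44 to 6.77 ± 2.45 CPM, -2.51 ± 0.2), Egr2 (-3.88 ± 0.35) and the synaptic scaffold gene Homer1 (-1.25 ± 0.08). That list did not stand apart with an estimated correlation (camera adjusted p = 0.42). Of 22 synaptic and pan-neuronal genes 15 fell and 4 rose (16 fell adjusted over the list alone; adjusted p = 0.078 with an estimated correlation). Of 18 astrocyte genes 13 fell and 2 rose, led by the glutamate transporter Slc1a2 (-1.09 ± 0.06), with adjusted p = 0.17 with an estimated correlation. Gpx6, a glutathione peroxidase gene, fell from 9.18 ± 3.78 to 0.0945 ± 0.0501 CPM (-6.46 ± 0.28) and Abhd11os, a striatum-enriched long non-coding RNA, by 4.89 on the log2 scale, the largest decreases among genes with a mean of at least 1 CPM.

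Metabolic and immune genes of the striatum changed in both directions. Cholesterol synthesis genes fell in 16 of 23 cases and rose in 0 (median -0.46, adjusted p = 0.0085 by camera with an estimated correlation), with Msmo1, a sterol oxidase (-1.12 ± 0.05), and Insig1, a sterol-responsive regulator (-1.06 ± 0.07), as examples. Of 19 circadian clock genes 15 fell and 2 rose (median -0.8, adjusted p = 0.00061 with an estimated correlation), among them the output regulator Dbp (-1.64 ± 0.08) and the core activator Npas2 (-1.19 ± 0.06). Interferon response genes went up: 21 of 23 rose and 0 fell (median 1.12, adjusted p = 0.036 with an estimated correlation), including the interferon regulator Irf7 (1.91 ± 0.74 to 7.37 ± 1.2 CPM, 1.96 ± 0.14, edgeR adjusted p = 2.3e-14). Smim24 (2.18 ± 0.14) was among the largest increases. In the kynurenine pathway Ido1, which opens tryptophan breakdown (-1.25 ± 0.11), and the aminotransferase Kyat3 (-0.48 ± 0.07) fell, and Afmid rose (1.26 ± 0.14). Kmo did not pass (-0.4 ± 0.32, edgeR adjusted p = 0.3), and 1 of 10 genes of the pathway rose and 3 fell (camera adjusted p = 0.97 with an estimated correlation). In all, 9826 of 17494 genes passed in the striatum by edgeR with Benjamini-Hochberg adjustment, 5189 up and 4637 down. With the authors' FPKM values the split was 8029 up and 2944 down, and the median gene shifted by 0.11 on that scale.

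**Figure D1:**
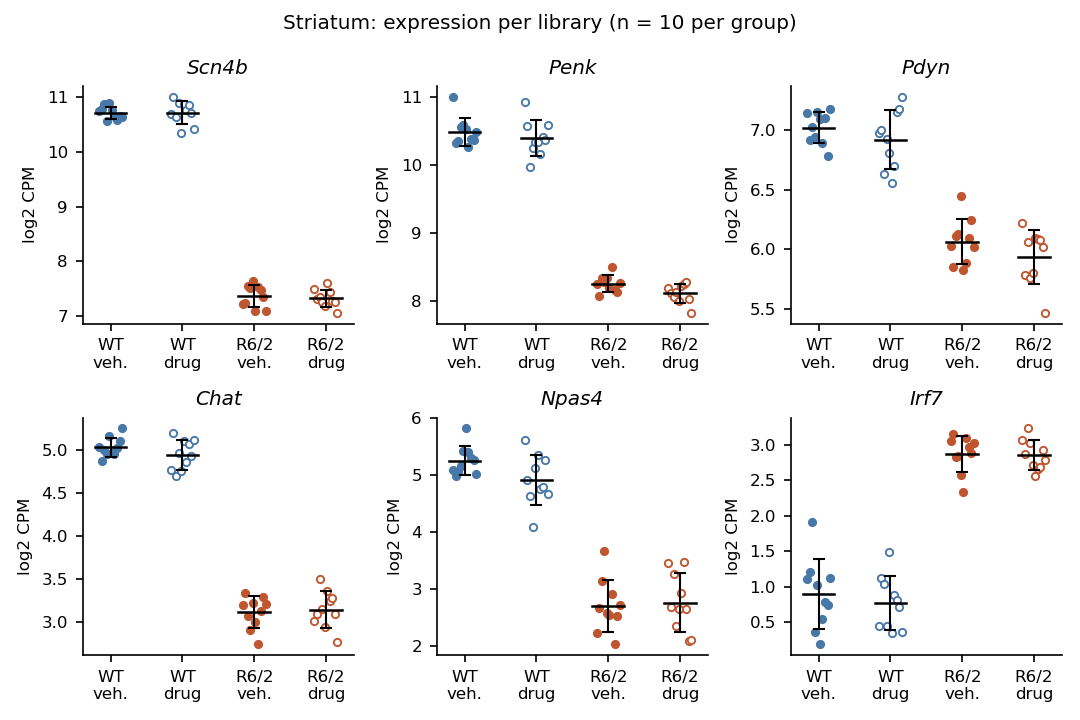
Log2 CPM of Scn4b, Penk, Pdyn, Chat, Npas4 and Irf7 in each striatum library by genotype and treatment (10 libraries per group; filled points vehicle, open points CHDI-00340246; bars mean ± SD). Scn4b, Penk, Pdyn, Chat and Npas4 were lower and Irf7 was higher in R6/2 libraries, with vehicle and with drug.

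In the cortex, peptides of interneurons and genes of projection neurons were lower in R6/2 animals. Vip (48.6 ± 5.04 to 15.6 ± 2.56 CPM, SD, n = 10 per group; log2 fold change -1.65 ± 0.08, SE, edgeR adjusted p = 2.6e-18), Sst (-1.44 ± 0.09, edgeR adjusted p = 3.3e-16) and Npy (-1.39 ± 0.08), the neuropeptides that mark separate interneuron classes, fell in 10 of 10 R6/2 libraries relative to the WT mean. Of 19 neuropeptide genes 16 fell and 0 rose (median -0.97, adjusted p = 0.035 by camera with an estimated correlation). Among 18 projection neuron genes 12 fell and 0 rose (median -0.48, adjusted p = 0.035 with an estimated correlation), including Lamp5, which also marks a class of interneurons (234 ± 40.1 to 47.8 ± 13.1 CPM, -2.31 ± 0.1, edgeR adjusted p = 9.9e-20), and the synaptic kinase Camk2a (-0.97 ± 0.05). Medium spiny neuron genes that the cortex also expresses, such as Scn4b (-2.7 ± 0.17), fell in 13 of 29 cases (adjusted p = 0.61 with an estimated correlation).

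Lists of activity, clock, sterol and interferon genes moved in the cortex as well. Immediate early genes fell in 17 of 22 cases with Npas4 (-1.81 ± 0.21) and Homer1 (-1.11 ± 0.12) among them, although the list did not stand apart with an estimated correlation (camera adjusted p = 0.62). Clock genes fell in 15 of 19 cases and rose in 2 (adjusted p = 0.0017 with an estimated correlation), with the repressor Bhlhe40 (-1.37 ± 0.07) and Dbp (-1.6 ± 0.1) as examples. Cholesterol synthesis genes fell in 21 of 23 cases (median -0.49, adjusted p = 0.044 with an estimated correlation), among them Idi1 (-0.78 ± 0.05) and Fdft1 (-0.79 ± 0.05). Astrocyte genes fell in 13 of 18 cases and rose in 2 (adjusted p = 0.044 with an estimated correlation), Slc1a2 by 0.83 on the log2 scale. Interferon response genes rose in 21 of 23 cases (22 adjusted over the list alone; median 1.05, adjusted p = 0.044 with an estimated correlation), with Irf7 going from 1.75 ± 0.423 to 7.36 ± 1.34 CPM (2.08 ± 0.14, edgeR adjusted p = 1.7e-15) and Ifi44 changing by 2.48 ± 0.18. The largest decreases included the lipoxygenase Alox12b (4.13 ± 0.793 to 0.238 ± 0.0898 CPM, -4.11 ± 0.18) and the kinase gene Plk5 (-3.3 ± 0.14), and the NAD-linked methyltransferase Nnmt rose (1.7 ± 0.19).

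Some developmental transcription factors with few counts in the WT cortex had more in R6/2. Pou4f1, a regulator of sensory neurons, had a mean of 0.0499 ± 0.0643 CPM in WT and 1.82 ± 0.481 CPM in R6/2 (SD, n = 10 per group, higher in 10 of 10 libraries). Of 39 listed Hox genes 5 reached the expression filter, which genes with almost no WT counts can do only through R6/2 libraries, so their shared direction is not evidence by itself, and the list did not stand apart with an estimated correlation (camera adjusted p = 0.15). Over 5 WT female and 5 WT male libraries Hoxb8 had 0 and 0 counts, against 76 and 29 in R6/2. Hoxb5 had 1 and 1 against 130 and 85, Hoxc4 0 and 0 against 48 and 27, and Hoxc6 0 and 1 against 45 and 25. The craniofacial factor Twist1 (2.59 ± 0.18) and the neural factor Onecut2 (2.16 ± 0.09, edgeR adjusted p = 1.6e-20) were among the largest increases. In the cortex 9658 of 17554 genes passed by edgeR, 4941 up and 4717 down, against 7104 up and 3376 down with the authors' FPKM values.

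The cerebellum showed a decrease of Purkinje cell genes and an increase of microglial genes in R6/2. Rgs8, a Purkinje-enriched regulator of G protein signalling (chromosome 1, 153653025 to 153700323), fell from 1448 ± 74.3 to 376 ± 23.5 CPM (SD, n = 10 per group; log2 fold change -1.94 ± 0.05, SE, edgeR adjusted p = 8.8e-29). Arhgef33 (-1.95 ± 0.05), the calcium channel Itpr1 (-1.71 ± 0.06) and the calcium-binding protein gene Pvalb (-1.38 ± 0.07) fell with it, each in 10 of 10 R6/2 libraries. All 17 measured Purkinje cell genes fell, with the same number adjusted over the list alone, a median of -1.46 and adjusted p = 2.1e-65 by camera (5.6e-08 with an estimated correlation). The GABA-synthesising enzyme Gad1 fell (-0.88 ± 0.03), and 7 of 11 GABAergic genes fell while 3 rose (adjusted p = 0.019 with an estimated correlation). Of 20 microglial genes 19 rose and 0 fell (median 0.63), among them the receptor Trem2 (2.58 ± 0.356 to 5.05 ± 0.723 CPM, 0.97 ± 0.1, edgeR adjusted p = 1.8e-10) and the protease Ctss (0.87 ± 0.09). The microglial list did not stand apart with an estimated correlation (camera adjusted p = 0.22).

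Interferon genes of the cerebellum rose in 21 of 23 cases (median 1.23, adjusted p = 0.045 with an estimated correlation), including Irf7 (1.65 ± 0.535 to 6.35 ± 0.657 CPM, 1.98 ± 0.1) and Ifit1 (1.95 ± 0.12). The signal transducer Stat2 was the only member that fell (-0.8 ± 0.03, edgeR adjusted p = 2.6e-21). Clock genes fell in 14 of 19 cases and rose in 3 (4 rose adjusted over the list alone; adjusted p = 0.0081 with an estimated correlation), with Bhlhe40 (-1.35 ± 0.07) among them. Cholesterol synthesis genes such as Idi1 (-0.95 ± 0.08) fell in 15 of 23 cases and rose in 2 (adjusted p = 0.41 with an estimated correlation). Immediate early genes went both ways, 10 of 20 down and 4 up, with Egr1 at -1.56 ± 0.14 and Jun at 0.8 ± 0.09. Of 18 mature oligodendrocyte genes 11 fell and 1 rose (adjusted p = 0.65 with an estimated correlation), whereas Gpr17, a marker of their precursors, rose (0.89 ± 0.09). The largest changes included Chrnb4, a nicotinic receptor subunit (-5.84 ± 0.34), the zinc finger gene Zfp92 (4.21 ± 0.18) and Rprm (3.55 ± 0.14). Kmo did not pass in the cerebellum (-0.06 ± 0.19, edgeR adjusted p = 0.8). By edgeR 8997 of 17206 genes passed, 4528 up and 4469 down, against 6121 up and 3425 down with the authors' FPKM values.

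Part of the genotype response recurred across brain tissues. Of 16469 genes tested in all 3 brain tissues, 2058 were higher and 1656 lower in each, and 716 passed in each with mixed directions. Striatum and cortex shared 3334 genes that rose, where independent lists of these sizes share 1480.5, and 2850 that fell, against 1192 for independent lists. Their fold changes correlated across genes at r = 0.69, and those of each with the cerebellum at 0.51, with genes not being independent replicates. The liver stood further away, with r = 0.12, 0.2 and 0.21 against the striatum, cortex and cerebellum. The tissues share no library, but the labels do not state whether they share animals, so the overlaps are not shown to be independent.

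**Figure D2:**
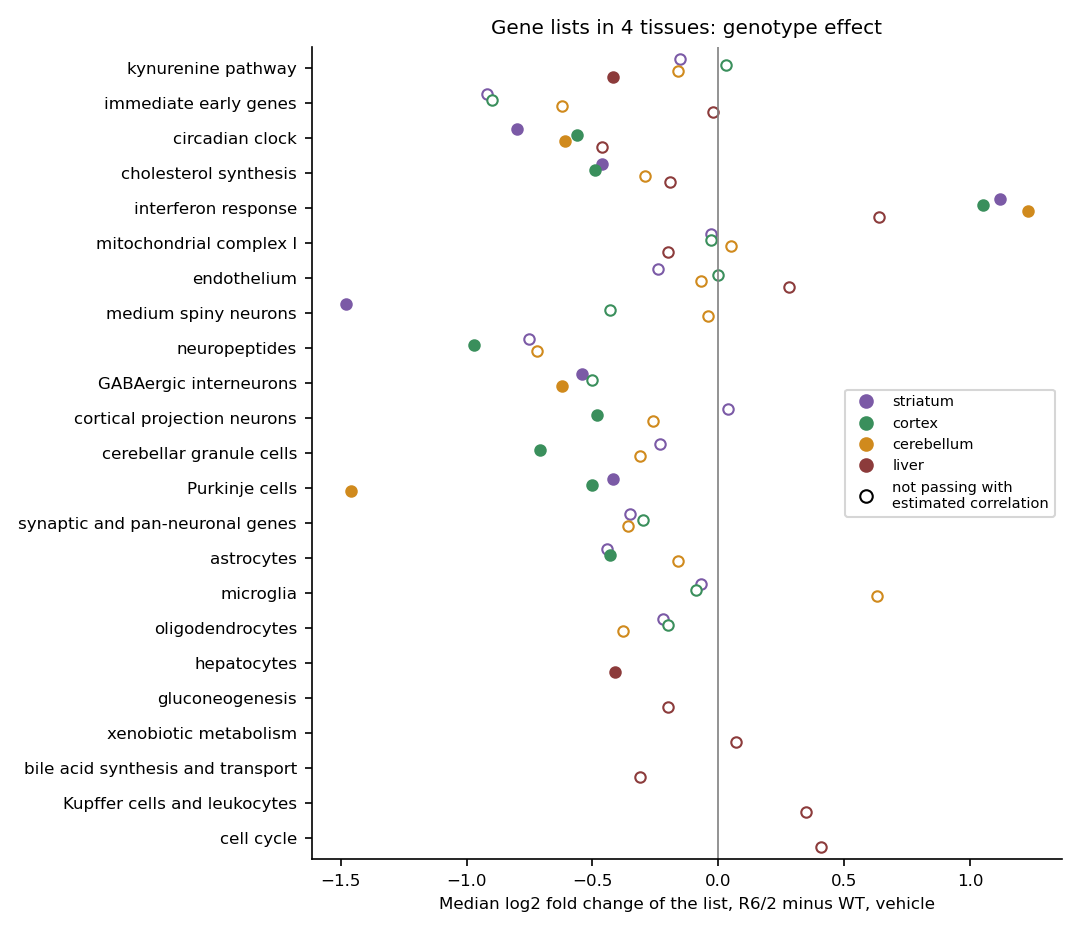
Median log2 fold change of each gene list, R6/2 over WT under vehicle, per tissue (n = 10 libraries per group; marker style shows whether the list test passed). The Purkinje list stood at -1.46 in the cerebellum, the medium spiny neuron list at -1.48 in the striatum and the interferon list between 0.64 and 1.23 in the 4 tissues.

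In the liver, genes that differ between the sexes changed most, and tryptophan-degrading enzymes were lower in R6/2 animals. The female-typical cytochrome Cyp2a4 rose (log2 fold change averaged over the sexes 5.07 ± 0.26, SE, n = 10 per group, edgeR adjusted p = 2.5e-16), and Cyp2b13 had a positive average (5.11 ± 0.33) that comes from males alone. Hsd3b1, a steroid dehydrogenase gene, went from 0.0898 ± 0.137 to 3.57 ± 2.48 CPM. The male-typical major urinary proteins Mup7 (-5.44 ± 0.38, edgeR adjusted p = 8.7e-13) and Mup20 (-4.03 ± 0.32), and the oxysterol hydroxylase Cyp7b1 (-1.71 ± 0.22) fell. The averages of the glutathione transferase Gstp1 (-1.8 ± 0.1) and the transporter Slco1a1 (-2.5 ± 0.47) were negative through males alone, as Slco1a1 went from 457.5 to 12.5 CPM in males and from 82.3 to 94.8 CPM in females. Of 25 female-biased liver genes 22 rose and 0 fell (adjusted p = 8.3e-09 by camera with an estimated correlation), and of 21 male-biased genes 20 fell and 0 rose (median -1.96, adjusted p = 2.2e-05 with an estimated correlation). Members of the Mup, Cyp2a, Cyp2b and Gstp families are near copies of each other, so that reads could be split among them, and their single values are uncertain. In a model with a shared sex term Cyp2b13 (edgeR adjusted p = 0.1) and Slco1a1 (0.074) did not pass, nor did they with a replicate block (0.15 and 0.11). With the authors' FPKM values Cyp2b13 (0.055), Slco1a1 (0.051) and Cyp7b1 (0.066) did not pass by limma. That fit has no sex term, so the sex difference adds to its spread, and these losses cannot be assigned to the unit.

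Kynurenine pathway enzymes, which the liver expresses strongly, fell in 10 of 12 cases and rose in 1, with the same numbers adjusted over the list alone (median -0.42, adjusted p = 0.0033 with an estimated correlation). Kmo itself went from 333 ± 47.8 to 249 ± 20.2 CPM (SD, n = 10 per group; -0.41 ± 0.07, edgeR adjusted p = 5.4e-05, lower in 10 of 10 R6/2 libraries). Tdo2, which starts tryptophan degradation in the liver, went from 1510.2 ± 479 to 722 ± 210.1 CPM (-1.01 ± 0.14, edgeR adjusted p = 2.2e-06). Kynu (-0.43 ± 0.07) and Aadat (-0.69 ± 0.12) fell too, while the aminotransferase Kyat3 rose on average (0.56 ± 0.12, edgeR adjusted p = 0.00087), from 102.5 to 228.1 CPM in males with 196 and 192.5 CPM in females.

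**Figure D3:**
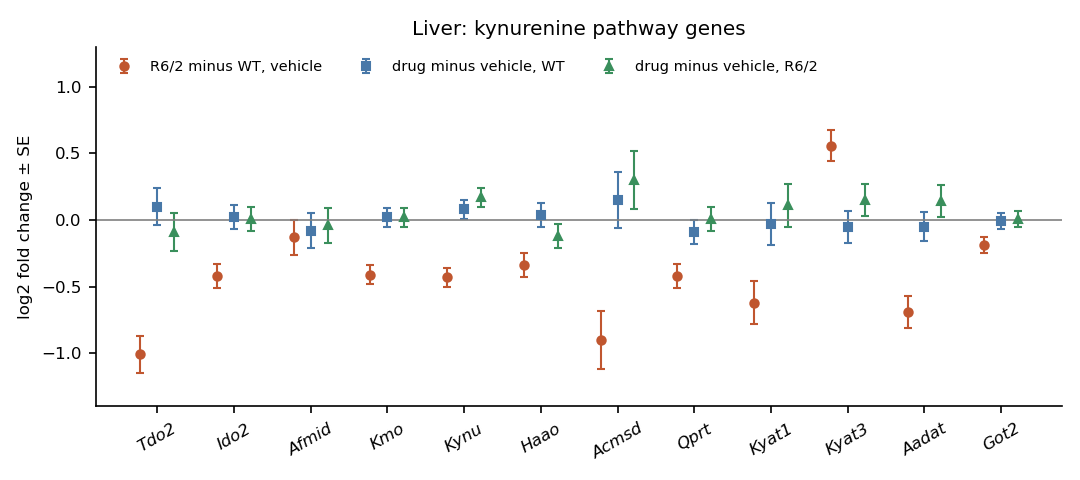
Log2 fold change ± SE of 12 kynurenine pathway genes in the liver for genotype under vehicle, drug in WT and drug in R6/2 (n = 10 libraries per group). Genotype values of 10 genes passed below 0, and none of the drug values passed by edgeR.

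Hepatocyte, clock and immune genes of the liver changed as well. Hepatocyte products such as the protease inhibitor Serpina1a (-0.68 ± 0.1) and the urea cycle enzyme Arg1 (-0.73 ± 0.12) fell, 10 of 20 listed hepatocyte genes falling and 1 rising (12 fell adjusted over the list alone; adjusted p = 0.019 with an estimated correlation). The core clock activator Arntl rose from 1.74 ± 0.759 CPM (2.88 ± 0.39, edgeR adjusted p = 2.3e-06), Cry1 rose (1.16 ± 0.16), and the repressor Nr1d1 fell (-1.83 ± 0.26). Of 19 clock genes 5 rose and 8 fell, and the list moved in no single direction (camera adjusted p = 0.092). Interferon genes rose in 15 of 23 cases and fell in 0 (17 rose adjusted over the list alone; adjusted p = 0.08 with an estimated correlation), among them Ifi44 (1.43 ± 0.18), Gbp3 (1.11 ± 0.14) and Irf7 (28.2 ± 8.53 to 56.5 ± 13.7 CPM, 1.01 ± 0.15). Genes of mitochondrial complex I fell in 18 of 36 cases (25 adjusted over the list alone; median -0.2, adjusted p = 0.42 with an estimated correlation). By edgeR 3890 of 15145 genes passed, 1956 up and 1934 down, against 4737 up and 352 down with the authors' FPKM values, on which the median gene shifted by 0.1. Without replicate 3 of every group the number was 2228.

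The balanced sexes allowed a test of whether the genotype acted differently in females and males. In the liver 648 genes passed this interaction, and the sexes of R6/2 mice were closer to each other than those of WT mice. Mup7 stood at 76.8 CPM in WT females and 24192 ± 7359 CPM in WT males (SD, n = 5 each), against 31.9 ± 22.4 and 30.8 ± 14.5 CPM in R6/2 females and males (interaction on the log2 scale 8.35 ± 0.72, SE, edgeR adjusted p = 3e-10). Gstp1 fell from 2087 ± 321 CPM in WT males to 164 ± 16.1 CPM in R6/2 males, the level of R6/2 females (165 ± 15.6 CPM; 3.73 ± 0.21, edgeR adjusted p = 1.8e-15). Cyp2b13 was near 0 in WT males (0.116 ± 0.108 CPM against 461 ± 233 CPM in WT females) and stood at 254 ± 89.1 and 264 ± 85.8 CPM in R6/2 females and males (-11.94 ± 0.68, edgeR adjusted p = 5.6e-15). Cyp2a4 went from 0.422 ± 0.116 CPM in WT males to 289 ± 76.5 CPM in R6/2 males (-8.65 ± 0.5). The steroid dehydrogenase Hsd3b5 (10.42 ± 1.15), Cyp7b1 (2.91 ± 0.44), the asparagine synthetase Asns (4.83 ± 0.81) and Kyat3 (-1.18 ± 0.24) passed too.

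Of the 21 male-biased genes 18 had a positive interaction and of the 25 female-biased genes 21 a negative one (2 lists with adjusted p = 2e-07 and 9.6e-13 by camera with an estimated correlation; 23 negative and 1 positive in the female-biased list adjusted over the list alone). In WT 1583 liver genes differed between the sexes under vehicle, 845 higher in females and 738 higher in males, and in R6/2 43 did by the same test. Without replicate 2 of every group 286 genes passed the interaction (Kyat3 not, edgeR adjusted p = 0.066), and without replicate 3 the number was 288. In the striatum, cortex and cerebellum 0 genes passed by edgeR (1091, 1692 and 540 at an unadjusted p under 0.05), and DESeq2 called 0, 1 and 0. The 3 genes with the smallest p did not pass in these tissues. They were the pituitary hormone genes Prl (11.7 ± 2.64) and Gh (11.93 ± 2.87) with Gskip (-0.4 ± 0.09) in the striatum (edgeR adjusted p = 0.73 in each). In the cortex they were Coro1a (0.45 ± 0.1), Tnfrsf11a (0.55 ± 0.12) and Aldh1a3 (-1.35 ± 0.3, edgeR adjusted p = 0.33 in each). In the cerebellum Rasgrp1 (0.43 ± 0.09, 0.87), Gm26801 (-0.89 ± 0.22, 1.0) and B230319C09Rik (1.25 ± 0.33, 1.0) came first.

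**Figure D4:**
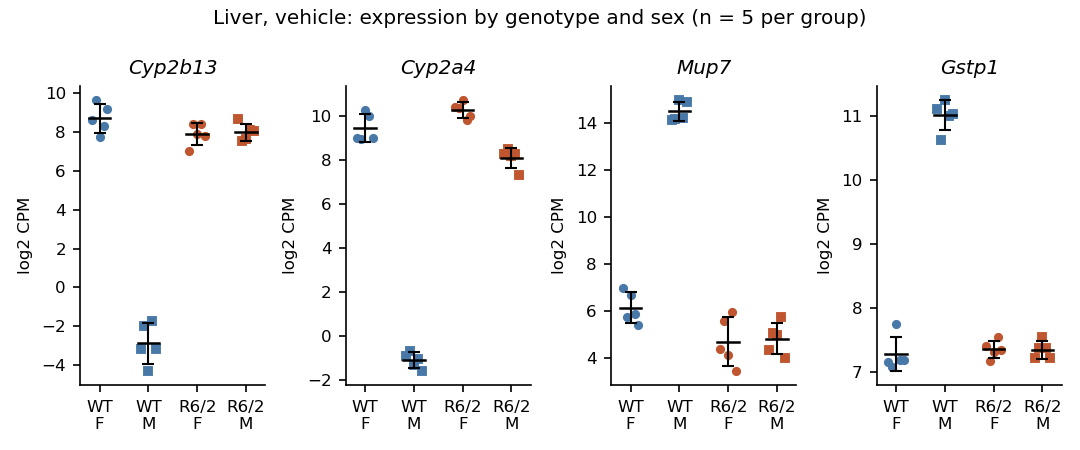
CPM on a log scale of Cyp2b13, Cyp2a4, Mup7 and Gstp1 in each vehicle-treated liver library by genotype and sex (n = 5 per group; bars mean ± SD). The sexes stood far apart in WT and close together in R6/2 for Cyp2b13, Mup7 and Gstp1.

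Few genes passed for CHDI-00340246 against vehicle 6 h after the dose. Folds of 1.25 simulated for the drug in R6/2 were recovered in 35.8 to 58.2% of cases, so changes of that size can be missed. Liver Kmo mRNA was 249 ± 20.2 CPM with vehicle and 252 ± 33.7 CPM with the drug in R6/2 (SD, n = 10 per group; log2 fold change 0.02 ± 0.07, SE, edgeR adjusted p = 0.98), and 333 ± 47.8 and 338 ± 59.9 CPM in WT. In WT animals 0 genes passed by edgeR in the striatum, cortex, cerebellum and liver (633, 1816, 1079 and 483 at an unadjusted p under 0.05), while DESeq2 called 7, 43, 2 and 5. The genes with the smallest p in WT did not pass. They were Gm5540 (4.09 ± 0.94), Irgm2 (-0.49 ± 0.11) and Dsp (1.42 ± 0.33) in the striatum (edgeR adjusted p = 0.78 in each). In the cortex they were Gm26723 (-2.3 ± 0.44, 0.2), Rcc2 (0.13 ± 0.03, 0.23) and Tnip1 (0.21 ± 0.05, 0.23). In the cerebellum Psmg4 (0.47 ± 0.1), Klrg2 (-0.74 ± 0.18) and Dgke (-0.18 ± 0.04) came first (0.77 in each), and Gm16534 (1.07 ± 0.23, 0.57), Snap47 (-0.48 ± 0.11, 0.91) and Cdk6 (0.61 ± 0.15, 1.0) in the liver.

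In R6/2 animals the drug effect passed for 0, 22, 7 and 11 genes in the striatum, cortex, cerebellum and liver by edgeR (DESeq2 11, 57, 21 and 25). The 3 genes with the smallest p in the striatum, Trim30d (-0.83 ± 0.16, edgeR adjusted p = 0.095), Dgat2 (-0.37 ± 0.08, 0.13) and Gzmk (1.44 ± 0.3, 0.13), did not pass, and DESeq2 passed all 3. In the cortex 6 genes rose and 16 fell. Pdyn went from 7.75 ± 2.65 to 3.79 ± 0.777 CPM (SD, n = 10 per group; -1.02 ± 0.17, SE, edgeR adjusted p = 0.0064). The hair cell and synaptic gene Otof went from 8.22 ± 2.64 to 3.62 ± 1.26 CPM (-1.18 ± 0.22, edgeR adjusted p = 0.019) and Arhgap36 from 2.22 ± 1.72 to 0.488 ± 0.184 CPM (-1.97 ± 0.38, edgeR adjusted p = 0.019). Foxp2, a transcription factor of deep-layer neurons (-0.47 ± 0.1), and the antiviral gene family members Trim12a (-0.77 ± 0.12) and Trim30d (-1.0 ± 0.19) fell, while Nnt, the mitochondrial transhydrogenase (0.25 ± 0.05), Prdm8 (0.25 ± 0.05) and the coat protein gene Copb1 (0.17 ± 0.04) rose. Near Nnt (chromosome 13, 119335448 to 119408997) lies 4833420G17Rik (119462768 to 119486120). In each brain tissue it stood at the lower of 2 levels in 2 R6/2 vehicle and 9 R6/2 drug libraries. Whether a variant shared out unevenly between the arms reaches Nnt was not tested. Genes enriched in the striatum moved alongside: of the 100 with the highest striatum to cortex ratio in WT, 89 were lower in the cortex of treated R6/2 (median -0.32) and 91 in that of treated WT animals (median -0.17). The medium spiny neuron list had a median of -0.28, with 1 gene falling and 9 adjusted over the list alone (adjusted p = 0.4 by camera with an estimated correlation). Over the alternative settings, the 26 named calls of the drug in R6/2 were kept in 193 cases and missed the threshold in 177, each time in the same direction. The Nnt call was lost with the library run as covariate (adjusted p = 0.053) or FPKM (0.065), and without replicate 1, 2, 3 or 4. That of Prdm8 was lost with additive sex (0.1), a replicate block (0.15), the library run (0.053) or FPKM (0.11), and without replicate 2, 3, 4 or 5. With the library run as covariate 0, 3, 1 and 3 genes passed in the striatum, cortex, cerebellum and liver. The named calls that it ended include Arhgap36 (-1.7, adjusted p = 0.12), Foxp2 (-0.43, 0.25) and Copb1 (0.17, 0.14) in the cortex and Dgat2 (-0.39, 0.33), Pold3 (0.32, 0.36), Aqp11 (-0.51, 0.48) and Neb (0.58, 0.71) in the liver, all with folds in the same direction, so these losses do not show that the run was their source. The cortex count was 0 without replicate 2, 1 without replicate 3, 2 without replicate 4 and 9 without replicate 5 of every group, and 34 genes without the 7 cortex libraries in which the pituitary hormone gene Gh exceeded 5 CPM.

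In the cerebellum of R6/2, the unconventional myosin gene Myo7a fell from 27.9 ± 5.09 to 17.1 ± 3.85 CPM with the drug (SD, n = 10 per group; -0.71 ± 0.13, SE, edgeR adjusted p = 0.023). This call was lost with additive sex (0.066), a replicate block (0.11), the library run as covariate (0.18) or FPKM (0.055), and without replicate 1, 2, 3 or 4 (0.21, 0.8, 0.1 and 0.22). The mitochondrial uncoupling gene Ucp2 (38.7 ± 11.8 to 23.6 ± 5.76 CPM, -0.68 ± 0.12), Trim12a (-0.83 ± 0.14) and the lipogenic regulator Thrsp (-0.39 ± 0.07) fell too, while Copb1 rose (0.23 ± 0.04). The Ucp2 call was lost with additive sex (0.061), the library run (0.15) or FPKM (0.16), and without replicate 1, 2, 4 or 5. That of Copb1 was lost with additive sex (0.066), a replicate block (0.072), the library run (0.22) or FPKM (0.12), and without replicate 1, 2, 3 or 4. Thrsp lost its call with the library run (0.097) or FPKM (0.055), and without replicate 1 or 4, and Trim12a without replicate 2 or 4. In the liver of R6/2, 7 genes rose and 4 fell. Dgat2, which makes triglycerides, fell from 484.5 ± 84.1 to 349 ± 11.8 CPM (-0.47 ± 0.08, edgeR adjusted p = 0.0056), and the aquaporin gene Aqp11 fell (-0.6 ± 0.12). Trim12c rose from 13.9 ± 2.48 to 20.7 ± 2.99 CPM (0.57 ± 0.09, edgeR adjusted p = 0.0025), as did the polymerase subunit gene Pold3 (0.39 ± 0.07) and Neb (0.74 ± 0.16). Of the 40 drug calls in R6/2 over the 4 tissues, 20 lay in a window of chromosome 7 that starts at 80 Mb and holds Trim12a, Myo7a, Copb1 and 1.57% of the tested genes. Its bounds were chosen after the calls were seen. Without the genes of this window 0 calls were left in the cerebellum and the liver and 15 in the cortex. The number without 1 replicate number ranged from 0 to 10 in the cerebellum, where leaving out replicate 4 gave 0 and replicates 1 or 2 gave 1. In the liver it ranged from 0 to 9, where leaving out replicates 2 or 3 gave 0.

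**Figure D5:**
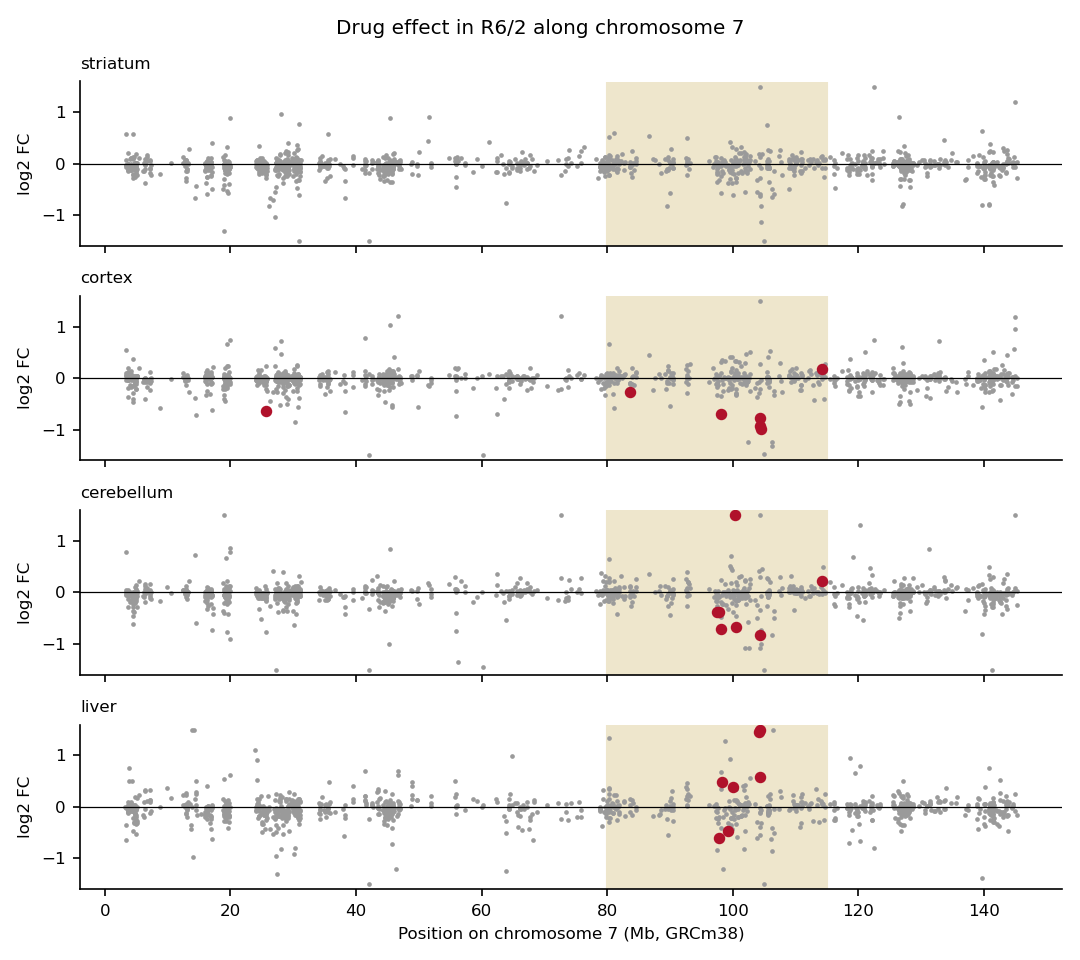
Drug effect in R6/2 (log2 fold change) of genes on chromosome 7 by position in Mb, per tissue, with genes that passed in red and the window that starts at 80 Mb shaded. In the window 6, 7 and 7 genes passed in the cortex, cerebellum and liver.

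Averaged over both genotypes, the drug effect passed for 33 genes in the cortex, 8 up and 25 down, 1 in the cerebellum and 0 in the striatum and the liver by edgeR (1435 and 1234 at an unadjusted p under 0.05 in these last tissues; DESeq2 13, 170, 11 and 18 in the striatum, cortex, cerebellum and liver). In the cortex Arhgap36 (-1.44 ± 0.26, edgeR adjusted p = 0.034), the endopeptidase gene Ecel1 (-1.3 ± 0.26), Dgkk (-1.33 ± 0.29) and Pdyn (-0.56 ± 0.11) fell and Tnip1 rose (0.16 ± 0.03). The cortex count was 0 without a filter, with a replicate block and with the authors' FPKM values (Arhgap36 adjusted p = 0.057, 0.057 and 0.14), and ranged from 1 to 9 with a replicate number left out. With the mean level of striatum-enriched genes in the model, chosen after the data were seen, 7 genes passed. Arhgap36 (-0.76, adjusted p = 0.074), Ecel1 (-0.65, 0.11), Dgkk (-0.55, 0.23) and Pdyn (-0.3, 0.14) did not. The gene in the cerebellum was Myo7a (-0.53 ± 0.09, edgeR adjusted p = 0.041), which lies in the chromosome 7 window. Its call was lost without a filter (0.087), with additive sex (0.17), a replicate block (0.22), the library run as covariate (0.29) or FPKM (0.054), and without replicate 1, 2, 3 or 4 (0.1, 0.52, 0.24 and 0.56). Genes with the smallest p that did not pass were Gm11127 (-0.49 ± 0.1), Dgat2 (-0.25 ± 0.05) and Atg16l2 (0.24 ± 0.05) in the striatum (edgeR adjusted p = 0.22 in each) and Gm12070 (-0.77 ± 0.15, 0.1), Aqp11 (-0.41 ± 0.09, 0.17) and Dgat2 (-0.25 ± 0.06, 0.17) in the liver. Genes of the choroid plexus, the tissue that makes cerebrospinal fluid, were higher in the cortex of treated WT animals, 12 of 14 adjusted over the list alone and 0 over all genes (median 1.47, adjusted p = 0.85 with an estimated correlation). Glucocorticoid-responsive genes had medians of -0.3, -0.22, -0.3 and -0.3 in the treated R6/2 striatum, cortex, cerebellum and liver (0, 1, 1 and 0 genes fell adjusted over the list alone; adjusted p = 0.35, 0.4, 0.45 and 0.48 with an estimated correlation). With an estimated correlation 0 lists passed in any tissue for the drug in WT and 0 for the drug in R6/2.

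Responses of the genotypes to the drug were also compared directly. The interaction of drug and genotype passed for 0 genes in each tissue by edgeR (456, 890, 921 and 382 at an unadjusted p under 0.05 in the striatum, cortex, cerebellum and liver; DESeq2 1, 0, 1 and 3). The genes that passed in R6/2 were thus not shown to respond differently in WT. The 3 genes with the smallest p in the cortex were Pdyn (-0.92 ± 0.23), Epb41 (-0.24 ± 0.06) and Trim12a (-0.67 ± 0.17, edgeR adjusted p = 0.93 in each), and Pdyn passed (-1.04, adjusted p = 0.023) without the libraries with Gh above 5 CPM. In the striatum they were Ddx4 (-1.2 ± 0.31) and 2 genes without a symbol, ENSMUSG00000095247 and ENSMUSG00000090407 (1.0 in each). In the cerebellum they were Gm128 (1.41 ± 0.32), Ndufc2 (-0.29 ± 0.07) and Zfp518b (0.23 ± 0.06, 0.83 in each), and in the liver Trim12c (0.61 ± 0.12, 0.31), Pold3 (0.45 ± 0.1, 0.44) and Dgat2 (-0.44 ± 0.11, 1.0). Across genes the drug effects in WT and R6/2 correlated at r = 0.274, 0.315, 0.299 and 0.269 in the striatum, cortex, cerebellum and liver (two-sided permutation p = 0.025, 0.0012, 0.031 and 0.0088; Benjamini-Hochberg adjusted over 8 tests 0.062, 0.0096, 0.062 and 0.035). Runs of library numbers were shared unevenly between the arms, and with the run as covariate, an alternative chosen after the data were seen, the values were 0.078, 0.272, -0.052 and 0.18 (p = 0.48, 0.0034, 0.68 and 0.096). In the cortex, where p stayed under 0.05, striatum-enriched genes were lower in treated animals of both genotypes, so this correlation is not shown to be a response to the drug. Differences between the tissues were not tested. Whether the drug moved the genotype-altered genes back towards WT was tested with separate R6/2 vehicle libraries for the genotype and the drug effect. The correlation of the drug effect with the genotype effect was 0.121, 0.116, 0.107 and 0.192 (permutation p = 0.097, 0.12, 0.15 and 0.14, adjusted p = 0.15 in each), where a move towards WT gives values below 0. These correlations are across genes, which are not independent replicates.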

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

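Chosen after the results were seen were the chromosome 7 window itself and the tests of its calls against random draws, of a drug response of its genes, of paralogs, of a variant shared out unevenly between the arms, of mislabelled sex and of striatal and pituitary tissue in the cortex samples.

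A library stood apart from the other 9 of its group (or the other 4 of its sex) by Dixon's test in 35 of 402 groups of values (8.7%), where chance gives about 1 in 20. The values below are the gap to the next library over the range of the group. For depth the highest library was R6/2 vehicle F4 in the cerebellum (0.5) and R6/2 vehicle M1 in the striatum (0.704). In the striatum WT vehicle F1 was highest for Penk (0.554) and lowest for Slc1a2 (0.497) and Htt (0.509), and WT vehicle M1 was highest for Npas4 (0.478). Of the R6/2 vehicle libraries F2 was lowest for Abhd11os (0.468), M4 highest for Atg16l2 (0.620), and M3 highest among males for Prl (1.0) and Gh (0.916). In the cortex WT vehicle M4 was highest for Hoxc6 (1.0) and R6/2 vehicle F1 lowest for Htt (0.542). R6/2 drug M5 was lowest for Nnt (0.610) and Copb1 (0.605), WT drug F5 highest for Dgkk (0.591), and for Tnfrsf11a WT vehicle F1 was lowest among females (0.802) and R6/2 vehicle M3 highest among males (0.724).

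In the cerebellum R6/2 vehicle F5 was lowest for Zfp92 (0.478), WT vehicle M3 for Gpr17 (0.475) and R6/2 vehicle M3 for Trim12a (0.619). For Myo7a R6/2 drug M5 was highest (0.751) and WT vehicle M2 (0.555) and WT drug M5 (0.468) lowest. WT drug M5 was lowest for Zfp518b (0.530), WT vehicle F1 for Gm26801 (0.765, females) and R6/2 vehicle F4 for B230319C09Rik (0.720, females). In the liver R6/2 vehicle F5 was lowest for Kmo (0.569), WT vehicle M3 highest for Aadat (0.601) and R6/2 vehicle M2 highest for Kyat3 (0.722, and 0.855 among males). WT vehicle M5 was highest for Kyat3 among males (0.750), WT vehicle F3 highest for Gstp1 among females (0.827) and R6/2 vehicle M5 lowest for Cyp2a4 among males (0.716). R6/2 drug M5 was lowest for Pold3 (0.598) and R6/2 drug M1 highest for Kmo (0.525).

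Some genes lay above the WT vehicle mean, taken over both sexes, in every R6/2 vehicle library of one tissue. In another tissue they lay below it in every such library. These differences between tissues were not tested. On the log2 scale the effects differed for Cyp7b1 by 1.85 (cerebellum minus liver), Gstp1 by 2.06, Nnmt by 2.73 and Tdo2 by 1.88 (cortex minus liver), and Kyat3 by 1.04 and 0.95 (liver minus striatum and cortex). Npas2 differed by 1.51 and 0.88 (cerebellum minus striatum and cortex) and by 4.98 and 4.35 (liver minus striatum and cortex). Rgs9 differed by 2.82 (cerebellum minus striatum). The liver effects in these differences are averages over the sexes. For Gstp1, Kyat3 and Cyp7b1 the sexes differed in the liver (interaction 3.73, -1.18 and 2.91), and the effects of Gstp1 and Kyat3 there came from males.

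Of the 40 genes that passed for the drug in R6/2 over the 4 tissues, 20, of 16 genes, lay in the chromosome 7 window that starts at 80 Mb, whose bounds were drawn around the calls. In 1000 random draws of 35 genes, the number called in any tissue that have coordinates, the fullest window of this width on any chromosome held at most 6. By tissue the window held 6, 7 and 7 calls in the cortex, cerebellum and liver, against at most 5, 4 and 4 in draws. The draws take genes as independent, although neighbouring genes can vary together. A response of these genes to the drug was first read from a mean over tissues, which stayed below 2 standard errors in WT, and by tissue only after that result was seen. It stays open. In treated WT animals the genes moved the same way by more than 2 standard errors in 3 of 4 tissues (0.11 ± 0.05, 0.1 ± 0.04 and 0.14 ± 0.05 in the cortex, cerebellum and liver, -0.03 ± 0.06 in the striatum). These standard errors were taken across the 15 or 16 genes and not across animals. Neighbouring genes of the same animals are not independent, so these values cannot decide. These shifts were smaller than in R6/2 (0.49, 0.65, 0.67 and 0.42). The genes and their signs were chosen by the R6/2 effect, which by itself makes the R6/2 values larger. The drug by genotype interaction called 0 genes in each tissue by edgeR (456, 890, 921 and 382 at an unadjusted p under 0.05 in the striatum, cortex, cerebellum and liver, and 1, 0, 1 and 3 by DESeq2). Reads shared between paralogs also cannot be told apart. Of the 16 genes 8 have no gene of the same symbol stem within 1 Mb and 8 have one. The stem was the leading letters of a symbol, which for P4ha3 is P alone. A shared stem thus need not mean a shared gene family, and this count cannot decide. A strain variant that differs between R6/2 animals cannot be told apart either, with a mean signed correlation within R6/2 groups of 0.17. It was 0.223, 0.135, 0.176 and 0.146 in the striatum, cortex, cerebellum and liver. Of random sets of other genes with small p, 1 in 20 exceeded 0.264, 0.236, 0.173 and 0.21. Where nearly all libraries of an arm share a level, as for Myo7a below, little variation within groups is left, so this test cannot decide. Within the WT groups the genes followed Myo7a in the direction of their drug effect in 45 of 59 pairs of gene and tissue (permutation p = 0.02, 0.01, 0.21 and 0.41 in the striatum, cortex, cerebellum and liver), and Myo7a was low in 1 of the R6/2 vehicle and 9 of the R6/2 drug libraries of each brain tissue, against 1 and 4 in WT, so the shift in WT also goes the way that a variant gives. A strain variant shared out unevenly between the R6/2 arms may therefore account for these calls, and these libraries cannot separate it from the treatment. The labels give C57BL/6J as the background of every animal and name no variant.

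In the liver 648 genes had a genotype effect that differed between the sexes, with values on the log2 scale of 10.42 for Hsd3b5, 8.35 for Mup7, 3.73 for Gstp1, -11.94 for Cyp2b13, -8.65 for Cyp2a4, 2.91 for Cyp7b1, -1.18 for Kyat3 and 4.83 for Asns. Mislabelled sex is argued against by the Xist and Ddx3y counts, which matched the label in 40 of 40 liver libraries. A few genes taking most of the counts is argued against by the 654 genes that passed without the 50 most abundant genes, which hold 37.5% of the counts. In the treated animals, which share no library with the vehicle groups, 99.8% of the 648 genes had an interaction of the same sign and 388 passed. An effect of the genotype on the sex difference may thus be proposed, as a hypothesis from the same data.

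In the cortex of treated R6/2, Pdyn and other genes were lower. Pituitary tissue in some samples is argued against, since 34 genes passed without the libraries with Gh above 5 CPM, against 22 with all. Less striatal tissue in the cortex samples of treated R6/2 may account for part of the pattern, as the 100 genes with the highest striatum to cortex ratio had a median drug effect of -0.32 and 89 were lower. With their mean level in the model 14 genes passed and 9 of the 22 were kept, Pdyn among them (from -1.02 ± 0.17 to -0.67 ± 0.12, edgeR adjusted p = 0.02), while Otof (-1.18 ± 0.22 to -0.78 ± 0.17, adjusted p = 0.058) and Arhgap36 (-1.97 ± 0.38 to -1.08 ± 0.23, adjusted p = 0.051) lost their call with smaller folds. A response of striatum-enriched genes to the drug stays open, as untested.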

How the results depend on the processing

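The library run covariate for the correlations and the leave-outs of the farthest library, of the chromosome 7 window, of libraries with Gh above 5 CPM and of libraries with Saa1 above 1000 CPM were chosen after the data were seen. The genotype counts under vehicle stayed within 1.5 times their value under all alternatives in the striatum (8690 to 10973), cortex (8595 to 10480) and cerebellum (7943 to 9588). In the liver they ranged from 2228 without replicate 3 to 5089 with FPKM. Of the genotype calls of 457 named genes, 6391 comparisons kept the direction and the threshold, 340 missed the threshold and 5 reversed. Those 5, all in the liver, were Gclm (0.04) and Taldo1 (0.02) with FPKM and Saa3 without replicate 5 (0.57), without libraries with Saa1 above 1000 CPM (0.25) and without the farthest library (0.41), and the cause was not tested. Of 48 named sex interaction calls 551 comparisons kept the threshold and 73 missed it. Of 14 named calls of the mean drug effect fewer comparisons kept it (83) than missed it.

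The drug counts moved with most settings, and the cause was not tested. DESeq2 called 7 genes in WT, 11 in R6/2, 13 for the mean effect and 1 for the interaction with genotype in the striatum, 43, 57 and 170 for WT, R6/2 and the mean in the cortex with 1 for the sex interaction, 2, 21, 11 and 1 in the cerebellum, and 5, 25, 18 and 3 in the liver. With FPKM the drug in R6/2 passed for 1, 6, 2 and 4 genes in the striatum, cortex, cerebellum and liver and the mean effect for 0, 0 and 1 in the cortex, cerebellum and liver. With additive sex 12 genes passed in R6/2 in the cortex and 2 in the cerebellum, and 0 for the mean in the cerebellum. With the library run as covariate 3, 1 and 3 passed in R6/2 in the cortex, cerebellum and liver, and 19 and 0 for the mean in the cortex and cerebellum. Without a filter, which adds tests, the mean passed for 0 genes in the cortex and 0 in the cerebellum and the drug in R6/2 for 4 in the liver. With the replicate block, which pairs libraries by replicate number, 2 and 4 genes passed in R6/2 in the striatum and cerebellum, and 0, 0 and 1 for the mean in the cortex, cerebellum and liver. Libraries of the same number had mean correlations of -0.015, 0.023, -0.009 and 0.028 in the striatum, cortex, cerebellum and liver, against 0.004, -0.006, 0.002 and -0.006 for other pairs. They were thus slightly closer in the cortex and the liver only. The closest library had the same number in 8, 15, 8 and 12 of 40 cases. These differences were not tested.

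Without libraries with Gh above 5 CPM the cortex had 3 genes in WT, 34 in R6/2, 1.1e+02 (rounded) for the mean and 2 for the interaction. Without libraries with Saa1 above 1000 CPM the liver had 6 in R6/2 and 2 for the mean. Without the farthest library the cerebellum had 2 for the mean. Without the genes of the chromosome 7 window it had 0 in R6/2 and 0 for the mean, and the liver had 0 in R6/2, where 7 of 7 and 7 of 11 calls lay in the window.

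With 1 replicate number left out, which removes 8 of 40 libraries, the drug in R6/2 passed for 0 to 2 genes in the striatum, 0 to 21 in the cortex, 0 to 10 in the cerebellum and 0 to 9 in the liver. The mean effect passed for 1 to 9 in the cortex and 0 to 1 in the cerebellum, and the interaction of drug and genotype for 0 to 1 in the liver. Saa3 ranged from -3.1 to 0.57 in the liver. The genotype effect in the liver passed for 2228 to 4046 genes and the sex interaction for 286 to 519.

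Of the list tests camera passed 45 for the genotype, 19 for the drug in WT, 33 in R6/2, 29 for the mean, 18 for the interaction and 26 for the sex interaction. With an estimated correlation these were 22, 0, 0, 0, 0 and 3, and fry passed 0, 0, 0 and 0 for the 4 drug contrasts and 4 for the sex interaction. The correlation of drug and genotype effects in R6/2 changed sign when both used the same R6/2 vehicle libraries, at -0.006, -0.01 and -0.016 in the striatum, cortex and cerebellum (p = 0.059, 0.058 and 0.09). Relabelled data average -0.163, -0.173 and -0.166 for this form, since shared libraries enter both effects with opposite sign, so the values lie above that average, on the same side as with divided libraries. The correlation of the drug effects in WT and R6/2, with the library run as covariate, was 0.078 in the striatum and 0.18 in the liver (p = 0.48 and 0.096), both weaker, and reversed at -0.052 in the cerebellum (p = 0.68). Simulated folds of 1.25 were recovered in 35.8% of cases for the drug in the liver, which limits small changes at this number of libraries.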

Other observations

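Tests of the transgene position, a strain variant around Gm12695, the clock phase, weakly expressed developmental regulators, the levels shared between libraries and their animals were chosen after the results were seen. Several lists of neuronal and liver genes have not been described above. In the striatum 9 of 18 neuropeptide genes fell and 0 rose (median -0.75, camera adjusted p = 0.17 with an estimated correlation), and of 17 Purkinje genes 9 fell and 2 rose (median -0.42, adjusted p = 0.049 with an estimated correlation). In the cortex 8 of 13 granule cell genes fell and 4 rose (median -0.71, 0.044 with an estimated correlation), 10 of 18 GABAergic genes fell and 1 rose (0.08), and 15 of 22 synaptic genes fell and 1 rose (0.15). In the cerebellum 7 of 11 neuropeptide genes fell and 0 rose (median -0.72, 0.08), and 9 of 14 granule cell genes fell and 3 rose (0.27).

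In the liver 8 of 17 bile acid genes fell and 0 rose (median -0.31, camera adjusted p = 0.16 with an estimated correlation), and 7 of 16 gluconeogenesis genes fell and 0 rose (median -0.2, 0.16). Of 20 Kupffer cell and leukocyte genes 7 rose and 0 fell (median 0.35, 0.43), and of 12 endothelial genes 6 rose and 0 fell (0.42). Of 31 xenobiotic genes 10 rose and 5 fell (0.43), and for the sex interaction 1 had a positive and 9 a negative value (median -0.51, 0.03 with an estimated correlation).

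Gm12695 (ENSMUSG00000078639, chromosome 4, 96723647 to 96785186) was detected in R6/2 at 3.25, 3.34, 2.64 and 2.8 CPM in the striatum, cortex, cerebellum and liver, against 0.0859, 0.0213, 0.0249 and 0 CPM in WT. In 80 of 80 R6/2 libraries it lay above the highest WT library of its tissue. A candidate explanation is that the transgene lies at this gene. A strain variant around the gene cannot be told apart from this. Genes within 5 Mb passed the genotype test in 82 of 179 cases (45.8%, against 48% elsewhere on the chromosome, Fisher p = 0.74). The rule first read this as evidence against such a variant. It was changed after the result was seen, since a variant that acts on Gm12695 alone would leave the rate as it is.

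In the liver 12 of 12 passing clock genes (100%) went in the directions that a shifted phase of the clock needs, and this may describe the liver pattern. In the striatum, cortex and cerebellum 13 of 14, 13 of 14 and 14 of 14 did. Each tissue was sampled at a single time, so a phase was not measured.

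A rise of weakly expressed developmental regulators in general was tested with genes chosen in treated WT libraries, which the genotype effect does not use. The genes had a mean below 1 CPM and at least 10 counts there, and genes not tested counted as not risen. In the cortex 15 of 55 developmental transcription factors rose and 1 fell, 27.3% rising against 9.4% of other such genes (one-sided Fisher p = 0.00015). In the striatum 8 of 63 rose (p = 0.29), in the cerebellum 4 of 59 (0.79) and in the liver 3 of 36 (0.74). This test replaced an earlier form after its result was seen, because the earlier form took genes past the expression filter, which R6/2 libraries can decide. That form gave p = 1.9e-07 in the cortex and 0.037 in the striatum. A rise may be proposed for the cortex, and whether the tissues differ was not tested.

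Some genes stood at separate levels within groups, in the same way in the 3 brain tissues. Of 12730 genes 81 had levels that matched between the tissues without an exception, and 0 did in each of 10 relabelled sets. They lay on 19 autosomes in 54 patterns, and 42 had predicted or pseudogene symbols. Examples are Glo1, Ide and Wdfy1. By these levels 40 of 40 striatum libraries had a cortex and a cerebellum library of their group and sex that equalled them at all 81 genes. These genes were kept for equal numbers of low libraries per group and sex, which does not fix which libraries pair. With as many other genes 0 libraries had such partners. Those genes were drawn from ones with unequal numbers, so this 0 was set in advance and decides nothing. Inherited sequence variants that differ between the animals are a candidate explanation. The labels give 1 inbred background, C57BL/6J, for every library, which goes against such variants unless the animals carry another background in part, and this was not tested. That the 4 tissues come from the same animals may be proposed as well, since 240 of 240 matched pairs held the same place in the specimen numbers of their tissues, which the match did not use. For the liver the matched libraries were equal at 93.8% of 78 genes on average, and at the lowest 85.9%. The overlaps between tissues described above would then rest on shared animals. The replicate numbers did not follow these matches, with 7 to 16 of 40 partners sharing a number where chance gives 8.

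Each count of genes was set beside 100 labelled sets of the libraries, the true one included, by limma-trend, under a rule written after the results were seen. For the genotype effect the true labels gave 9650, 9321, 9376 and 3416 genes in the striatum, cortex, cerebellum and liver, and the highest of the others 4175, 0, 60 and 1029. Only the true set, 1 of 100, gave as many in each tissue, which argues against chance. For the drug in R6/2 the true labels gave 4, 16 and 5 in the striatum, cortex and liver against a highest other of 2, 13 and 1, with 1 of 100 sets as large in each. That is the smallest share that 100 sets can give, and 24 counts were compared in this way. It argues against chance for these counts but does not exclude it. An uneven share of variants or of library runs, which the sets do not follow, is not excluded either. By edgeR the counts were 0, 22 and 11, and 0, 3 and 3 with the library run as covariate. In the cerebellum the true labels gave 11, and 3 of 100 sets gave as many, 1 of them 3376. A set that calls so many genes points to a structure of the samples in the R6/2 cerebellum. For the sex interaction in the liver the true labels gave 501 against 51, with 1 of 100 as large. These sets moved the sex labels within each genotype, which removes the sex difference itself along with the interaction. The comparison therefore cannot decide about chance for the interaction.

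For the other counts the true labels gave 0 by limma-trend, so that 100 of 100 sets gave as many by construction. Chance is not excluded there, and nothing is decided about the counts of the mean drug effect by edgeR (33 in the cortex, 1 in the cerebellum). The highest others were 688 (drug in WT), 2 (mean drug effect), 1 (interaction of drug and genotype) and 527 (sex interaction) in the striatum, 221, 3, 4 and 13 in the cortex, and 78, 6, 1 and 3 in the cerebellum. In the liver they were 4, 3 and 1 for the drug in WT, the mean and the interaction. Sets that call 688, 527 or 221 genes where the true labels call 0 point to a structure of the samples as well, one that does not follow the drug or the sex interaction.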
